A study of Nicotiana attenuata with 12 samples.

How the data were processed

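Gene expression was measured in pith of the root-shoot junction of Nicotiana attenuata, a wild tobacco, harvested at early flowering from plants with an empty vector (EV, the control, given as wild type in the labels) and from ir-max2 lines 107 and 136. The ir-max2 lines are independently transformed RNA interference lines, each with a single T-DNA insertion per the series' design text. There were 4 biological replicates per group per the design text, and each replicate was hybridized to its own Cy3-labelled 1-colour Agilent array, 12 arrays in all. The labels' treatment protocol and tissue field name root-shoot junction pith, whereas their extract protocol speaks of leaves. The tissue is given here as the treatment protocol has it.

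The scanner files hold spot intensity values on a linear scale, which per the file headers were made with Feature Extraction 10.7.3.1. The submitters' processing notes name version 9.5 of the same program. The processed intensity column was background-subtracted and detrended within each array by that program, per the file headers. The table of values deposited by the authors is on a log2 scale. How it was made is not given in the sources used here. Each of its columns correlated at 0.9999977 or more across probes with quantile-normalized log2 median spot intensity without background subtraction. That comparison bears on probe order and logarithmic form, and not on centring, since a correlation does not change with a shift. The column medians of that table lay between 7.04 and 7.07.

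Each array held 62976 spots, of which 1319 were control spots and were left out after reading. The remaining 61657 spots covered 57157 probes, 500 of them printed on 10 spots. Across the 12 arrays 1942 spots with an outlier flag were left out, no spot was saturated (0 of all spots), and spots of 1 probe were averaged on the log2 scale. Expression was the log2 processed signal minus each array's 75th percentile. Probes well above background on at least 4 of the 12 arrays were kept, which left 35992 probes of 25527 gene IDs. For arrays, the number of replicates limits the precision.

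One linear model with a mean for each of the 3 groups was fitted to the 12 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes). The contrasts were line 107 minus EV, line 136 minus EV, the mean of both lines minus EV, and line 136 minus line 107. P-values were two-sided and adjusted over all kept probes by the Benjamini-Hochberg method, and a probe was called at an adjusted p under 0.05. Array-level measures were compared by exact permutation tests. The samples, contrasts, tests of the contrasts and most alternatives were fixed before the data were examined, as was the naming rule apart from the condition given below. Plots were drawn with matplotlib 3.10.9.

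The fit was tested on simulated data drawn from the means and spreads of the real probes, in which 200 of 35974 probes with no missing value were given known changes in both lines. For the mean of both lines against EV, 20 of 50 probes changed by 0.5 on the log2 scale were called with the right sign, 39 of 50 changed by 1, 46 of 50 changed by 2 and 46 of 50 changed by 3. In that simulation 19 unchanged probes were called in the same contrast. Beside the 20, 39, 46 and 46 right calls, that is a larger share of false calls than the adjusted threshold aims at. With so few changed probes the Benjamini-Hochberg cutoff is stricter than in the real fit, where 17951 of 35992 probes were called. The recovery rates therefore hold for the simulated share of changed probes and do not give those of the real fit.

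The files do not pair probe IDs with gene names. None of the IDs (0) matched the gene table supplied for the species, which lists 39977 genes of another assembly. The level of MAX2, the silenced gene, is therefore not reported here, and the group labels were not checked against it. The gene lists fixed beforehand, for hormone, defence, cell wall and other functions, had 0 members to test for the same reason. Under the naming rule for this case at most 2 IDs that rose and 2 that fell are printed. They are the largest changes of the mean contrast among gene IDs called in both lines, and, as a condition set after the data were seen, well above background on at least 1 array of every group. This left 8270 of 9066 IDs. A gene ID with several probes was represented by its brightest probe.

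Slide and position on the slide were read from the file headers. Each of the 3 slides held 4 arrays and all 3 groups. Each slide was its own scan, so slide and scan cannot be told apart. EV arrays lay at positions 1 and 2, line 107 arrays at positions 2 and 3, and line 136 arrays at positions 3 and 4.

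Alternatives were normexp background correction with an offset of 50, quantile normalization, median scaling, the authors' value table, other filters, slide, position or replicate number as a block, fits of only the groups compared, another variance model, other thresholds, and leaving out each array. The normexp alternative had been planned on mean spot signals, a column not used here, and was run on median spot signals. Scaling to spiked-in control probes, leaving out whole slides or a pair of arrays, and the alternatives for detection were added after seeing the data.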

Results

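Expression was profiled in pith of the root-shoot junction of EV plants and of 2 independently transformed ir-max2 lines, 107 and 136, of Nicotiana attenuata at early flowering. MAX2 encodes an F-box protein of strigolactone and karrikin signalling, and the series title concerns strigolactones, jasmonates and auxin in defence against a stem-boring weevil. Each group had 4 arrays. Between 33837 and 36540 of 57157 probes were well above background per array. Arrays of the same group correlated at 0.972 to 0.993 across kept probes, arrays of the different lines at 0.977 to 0.988, and EV with line arrays at 0.916 to 0.957.

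Genotype was the main axis of variation. The first principal component held 67.6% of the variance and placed EV at a mean of -121 ± 9.02 (SD, n = 4), line 107 at 62.0 ± 31.0 (SD, n = 4) and line 136 at 59.3 ± 7.61 (SD, n = 4). No EV array overlapped a line array, the nearest being EV replicate 4 at -108 and line 107 replicate 2 at 23.9. The second component held 8.10% and ordered the slides, with 90.2% of its variance between slides.

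**Figure D1:**
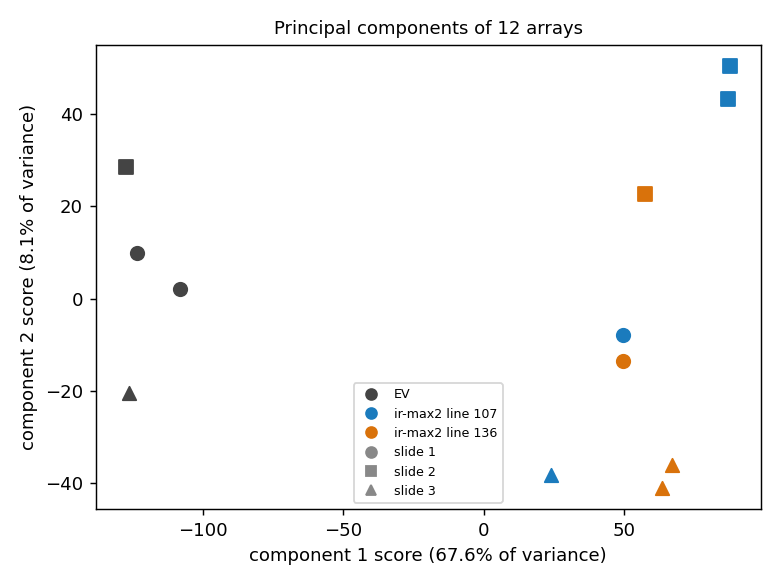
Scores of the 12 arrays on the first (x axis, 67.6% of variance) and second (y axis, 8.10%) principal components of the kept probes, with colour for group and shape for slide. EV arrays lie between -127 and -108 on the first component and line arrays between 23.9 and 87.8.

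Both ir-max2 lines differed from EV across much of the measured transcriptome. In line 107, 7447 probes rose and 8290 fell, and in line 136, 7236 rose and 8336 fell, of 35992 tested (limma, Benjamini-Hochberg adjusted p under 0.05, n = 4 per group). Many of these changes were small: the median size among called probes was 0.60 on the log2 scale in each line. At least 2-fold changes numbered 3268 up and 1489 down in line 107, and 3192 up and 1354 down in line 136. Position on the slide nearly followed group, and with position as a block the counts were 2716 in line 107 and 502 in line 136. That fit compares EV with line 107 only at position 2. There 1 EV array lay on slide 1 and the 2 line 107 arrays on slides 2 and 3. Line 136 shares a position with line 107 alone, so its contrast with EV is indirect. Few arrays thus inform either contrast under that block. Among the 12162 probes called in both lines, that block left the median fold change of their mean at 0.868 of its size. It left 99.6% of signs the same, while the SE was 2.38 times as large. Since the same arrays chose these probes, their sizes and signs do not decide whether position plays a part. Scaled to spiked-in control probes instead, the counts were 8786 in line 107 and 8103 in line 136. Left out as a whole, slide 2 brought line 107 to 8030 calls and slide 3 brought line 136 to 8512.

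The use of independent lines guards against effects of the insertion site, and most changes were common to both. The same direction was called in both lines for 12162 probes, 5916 up and 6246 down, and opposite directions for 13. Of the calls in line 107, 77.3% were also made in line 136 in the same direction, and 78.1% the other way round. Large changes were mostly rises: at least 2-fold in both lines, 2772 probes rose and 953 fell, and at least 8-fold, 688 rose and 61 fell. Detection on 4 of 12 arrays lets dim probes that rose in the 8 line arrays pass the filter more easily. How much of this excess of large rises comes from the filter was not tested. By gene ID, 4608 rose and 4458 fell in both lines. Independent lists of these sizes would share 1497 probes up and 1920 down. In 20 simulations of unchanged groups against the shared EV arrays 0 probes were called in both. Their noise was independent between probes and held no slide or position effect, so almost no calls were bound to follow. With separate pairs of EV arrays for each line, 4558 to 5438 probes were called in both, against 999 to 1230 for independent lists. With position as a block 460 probes were called in both, without slide 2 6817 and without slide 3 7636.

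Fold changes of the lines correlated across probes, which are not independent replicates, at a Pearson r of 0.945 and a Spearman rho of 0.873. Simulated unchanged groups gave a mean r of 0.499 because the EV arrays are shared, and separate pairs of EV arrays gave 0.862 to 0.905. The covariance was 0.886, against 0.0304 in the simulation. Taken within each slide, on separate arrays, the fold changes of the lines against EV correlated at 0.878, 0.895 and 0.844 between slides.

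**Figure D2:**
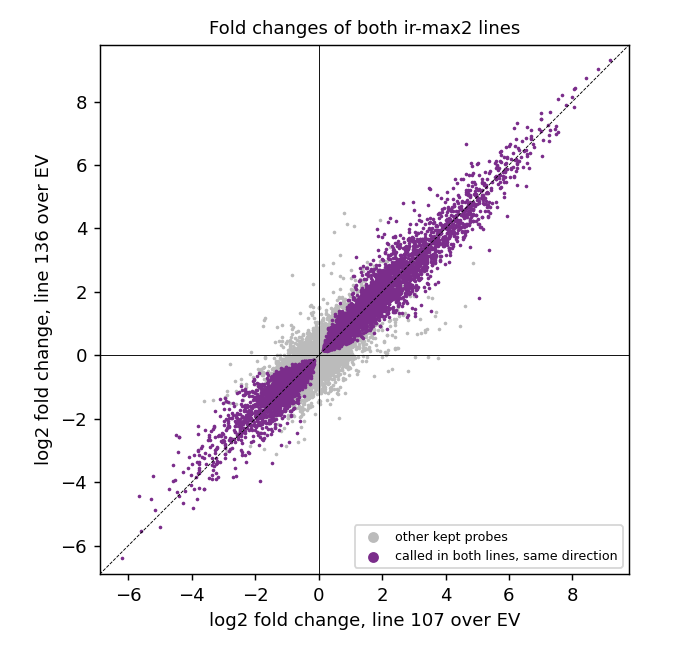
Log2 fold change over EV of each kept probe in line 107 (x axis) and line 136 (y axis), with probes called in both lines in the same direction in purple and the dashed line marking equal change. The points lie along that line, with r = 0.945.

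Tested as the mean of both lines, 17951 probes (49.9%) differed from EV, 8213 up and 9738 down (limma, Benjamini-Hochberg). The count was 18596 with slide as a block, 1792 with position as a block and 10332 when scaled to spiked-in control probes. The share of rises among these calls was 45.8%, and it depended on the scaling and on the block. With position as a block and the scaling unchanged it was 66.2%, with 1186 up and 606 down. Among calls in both lines 352 then rose and 108 fell. Without a block, rises made up 70.4% of the calls of at least 2-fold. The median log2 fold change of all kept probes was -0.03 with the position block. The higher share of rises among its fewer calls therefore does not show a turn of the response towards rises. Median scaling gave 22.6%, and spiked-in probes gave 66.9%, since the median log2 fold change of all kept probes was -0.04 in the main scaling, -0.27 under median scaling and 0.10 against the spiked-in probes. Directions of small changes are therefore relative to the 75th percentile of each array.

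The probe NIATv7_g00327.t1.cds1 rose by a log2 fold change of 8.58 (SE 0.85, limma adjusted p = 1.92e-05, n = 4 per group) in the mean of both lines, with 8.43 in line 107 and 8.73 in line 136. NIATv7_g18062.t1.cds1 rose by 8.22 (SE 0.63, limma adjusted p = 3.16e-06). Each was well above background on 2 of 4 EV arrays and on all 8 line arrays. With EV values raised to the lowest signal well above background on their arrays, the rises came to 223-fold and 245-fold, in which the other 2 EV arrays enter only as bounds. NIATv7_g05797.t1.cds1 had a log2 fold change of -5.05 (SE 0.39, limma adjusted p = 3.37e-06) and NIATv7_g08580.t1.cds1 one of -4.47 (SE 0.47, limma adjusted p = 2.84e-05). Both were well above background on all 12 arrays. Within slides, with EV values raised in the same way, the log2 fold change ran from 6.03 to 9.53 for NIATv7_g00327.t1.cds1, not well above background on the EV arrays of slides 2 and 3, and from 6.85 to 8.71 for NIATv7_g18062.t1.cds1, not so on 1 EV array of slide 1 and that of slide 3. It ran from -6.47 to -4.15 for NIATv7_g05797.t1.cds1 and from -5.53 to -3.95 for NIATv7_g08580.t1.cds1. With position as a block, NIATv7_g00327.t1.cds1 had 5.94 (limma adjusted p = 0.114) and NIATv7_g08580.t1.cds1 had -4.09 (limma adjusted p = 0.107), neither past the threshold, and NIATv7_g18062.t1.cds1 had 5.93 (limma adjusted p = 0.0217). Sizes depended on the processing, where background treatment was not changed alone. Under normexp, which also used another spot signal, the log2 fold changes were 6.27 for NIATv7_g00327.t1.cds1, 5.98 for NIATv7_g18062.t1.cds1, -3.50 for NIATv7_g05797.t1.cds1 and -4.07 for NIATv7_g08580.t1.cds1. In the authors' table they were, in the same order, 6.62, 6.37, -3.80 and -4.17. NIATv7_g00327.t1.cds1 had 7.72 without EV replicate 2 and 9.34 without EV replicate 4, and NIATv7_g18062.t1.cds1 had 8.92 without EV replicate 4.

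**Figure D3:**
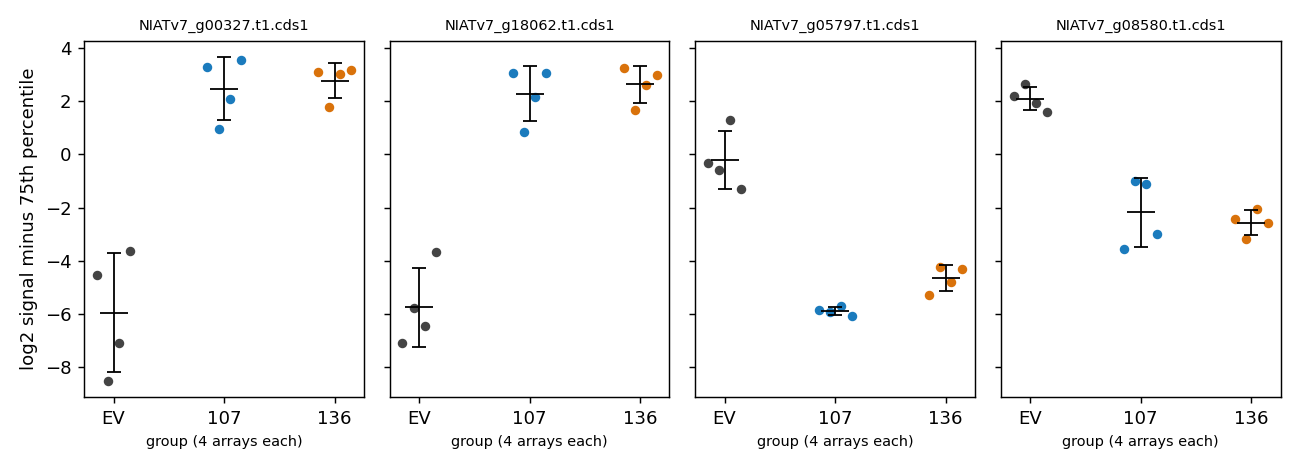
Log2 signal minus the 75th percentile of the array (y axis) for the 4 named probes in EV, line 107 and line 136 (x axis), each point an array and each bar the mean with its SD (n = 4). NIATv7_g00327.t1.cds1 and NIATv7_g18062.t1.cds1 lie higher in both lines, and NIATv7_g05797.t1.cds1 and NIATv7_g08580.t1.cds1 lower.

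Probes detected in a single genotype were mostly those of the ir-max2 lines. On all 8 line arrays and no EV array, 506 probes of 476 gene IDs were well above background, against 71 probes of 68 IDs for the reverse. When the same number of probes was counted as detected on every array, the counts were 386 and 121. With equal numbers of arrays, 613 probes were detected on all line 107 arrays and no EV array and 96 the other way round, and 643 and 122 for line 136. The median probe of the 506 was at least 4.95-fold brighter in the lines, and 146 were at least 8-fold brighter. These bounds set EV to the higher of the probe's own signal and the lowest signal well above background on each array. The share of detected probes was 59.95% ± 0.60 in EV, 62.3% ± 1.58 in line 107 and 61.3% ± 0.64 in line 136 (SD, n = 4; exact permutation p = 0.0286 for each line against EV, the smallest the design allows, adjusted p = 0.0429). A test over the 3 groups together did not pass (exact permutation adjusted p = 0.118 over 6 measures), and 55.99% of the variance of this share lay between slides (exact permutation adjusted p = 0.0449). The line 107 arrays of slide 2 had 63.3% and 63.9%, and those of slides 1 and 3 had 60.9% and 61.0%. Within slides 1, 2 and 3 the line arrays averaged 60.8%, 63.1% and 61.0%, against 59.6%, 60.7% and 59.95% in EV. On slides 1, 2 and 3 the ratio of line-only to EV-only probes was 2.86, 2.53 and 1.74, with equal numbers of EV and line arrays on slide 1 alone. There, with the same number of probes counted as detected on every array, 705 probes were line-only and 507 EV-only.

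The lines differed less from each other than from EV. Line 136 was higher than line 107 for 190 probes and lower for 164, 354 in all (limma, Benjamini-Hochberg), of which 60 and 53 changed at least 2-fold. Among the 354, 246 were called against EV in a single line, 92 in both lines in the same direction, 13 in opposite directions and 3 in neither. Over all kept probes the SD of the log2 fold change was 0.32 between the lines and 0.95 for the lines against EV. Before adjustment 5190 of 35992 probes had a limma p under 0.05 between the lines. Smaller differences may therefore lie below the adjusted threshold, and their source was not tested. The count of 354 fell when any single array was left out. It ran from 69 without line 136 replicate 4 to 230 without EV replicate 4 over 10 of the arrays. It was 248 without EV replicate 3 and 282 without EV replicate 2. EV arrays enter this contrast only through the estimate of the spread. How much of the fall comes from fewer arrays alone was not tested. Over the 354, slide as a block gave a median fold ratio of 0.997 and an SE ratio of 1.04. With that block the count was 170, and 142 of the 354 were still called. It was 3 with position as a block, 38 without slide 2 and 3 without slide 3, and the differences between the lines within each slide correlated at 0.186, 0.288 and 0.0872 between slides.

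Control probes also differed by slide. The log2 signal of DCP_1_7 relative to DCP_1_0 averaged -4.34 ± 0.05 on slide 1, -3.42 ± 0.02 on slide 2 and -5.25 ± 0.09 on slide 3 (SD, n = 4), with 99.5% of its variance between slides (exact permutation p = 0.000173 over 5775 partitions, adjusted p = 0.000519 over 6 measures). Spiked-in control probes did not differ detectably between groups, at 9.87 ± 0.18 in EV, 9.87 ± 0.16 in line 107 and 9.87 ± 0.20 in line 136 (log2, SD, n = 4; exact permutation p = 1 and p = 0.943 against EV).

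**Figure D4:**
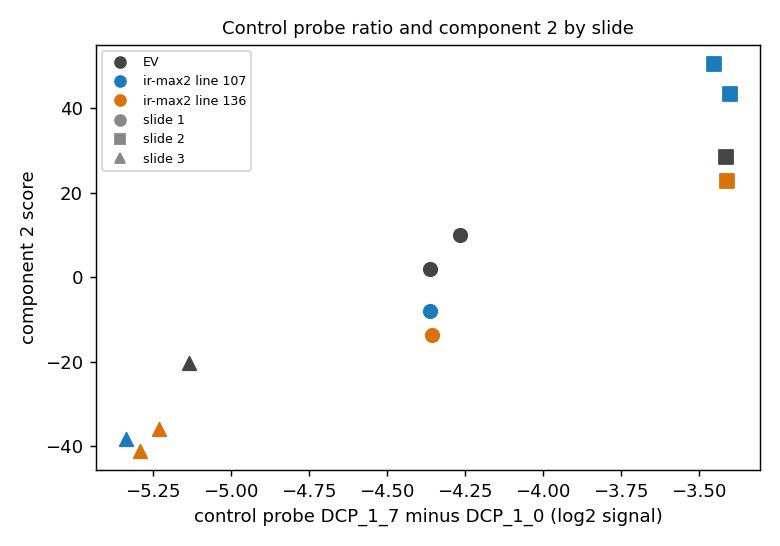
Log2 signal of control probe DCP_1_7 minus DCP_1_0 (x axis) and score on the second component (y axis) of the 12 arrays, with colour for group and shape for slide. The slides form separate clusters, at means of -4.34, -3.42 and -5.25 on the x axis, each with arrays of all 3 groups.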

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

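The tests of position, slide and scaling for the broad difference, of hybridization stringency, of slide as the whole cause of the line difference, of that cause on held-out arrays, of regroupings within slides, and of position and of slide for detection except the lowest ratio within a slide were chosen only after related results had been seen.

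The broad difference between EV and both ir-max2 lines exceeded every other grouping drawn. The real split was the 1 with as many calls among 35 for line 107 (15737, next 3), among 35 for line 136 (15572, next 1), and among 100 regroupings for the mean (17951, next 4) and for both lines together (12162, next 1); of 100 regroupings within slides, the 3 that exchanged the lines and kept EV gave up to 17226 and 11985, and the others at most 1, so chance can be excluded. Position as the cause is argued against by fold changes of line 107 over EV within position 2 alone. They correlated at 0.843 with those of line 136 at position 4 over EV at position 1. Position 2 held a single EV array, on another slide than its line 107 arrays. Slide as the cause is argued against by fold changes taken within slides, whose lowest correlation between slides was 0.844. Scaling as the whole cause is argued against by at least 3423 probes called in the less frequent direction under 5 other scalings, a test added because the count itself stayed undecided, at 10332 against spiked-in probes, between the bounds set for it. A response to MAX2 silencing is a hypothesis that the design names, but the silencing itself was not measured here. How many probes respond cannot be told apart from scaling and position. With position as a block 1792 were called for the mean and 460 in both lines.

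The change against EV differed between line 136 and line 107 for 354 probes by the test of the difference itself. Over the 35 splits, which ignore slide, the real split was the 1 with as many calls and the next gave 6. That share lies under 0.05 but is the smallest that 35 splits allow. The 18 of these that keep the arrays per slide of each line are too few for a share under 0.05. There the next gave 0, and chance is not excluded once slide is kept. Slide stays open: over these probes the line difference correlated at 0.0905 with EV replicate 3 minus EV replicate 2 (95% bootstrap interval -0.10 to 0.29), 60.5% shared its sign, the slides differed in control probes (99.5% of the variance), and with slide as a block 142 were still called at a fold ratio of 0.997 over all 354, while this and the ratio of 0.954 within slide 1 decide nothing because the same arrays chose the probes. On 55 probes chosen without the line arrays of slide 1, those arrays differed in the same direction for 90.9%, with a median ratio of 0.656, and within position 3 the ratio was 0.493 with 93.8% in the same direction (only 15 probes were called without those arrays, so the 354 with the smallest p were taken); both lie between the bounds set. Slide, position and a difference between the transformed lines therefore cannot be told apart for the size of this difference.

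More probes were detected on all ir-max2 arrays and no EV array than the reverse, 506 against 71. Brighter line arrays are argued against as the whole cause by a ratio of 3.19 when the same number of probes was counted as detected on every array. Position is argued against because 99.1% of 637 such probes chosen at other positions were brighter in line 107 than in EV within position 2. The single EV array there lay on another slide than the line 107 arrays. Unequal array numbers are argued against because 2 of 495 choices of 4 arrays as EV gave a ratio as large as 7.13; the other choice rested on 8 probes. Slide as source of the 506 is argued against by the layout, since every slide held EV and line arrays. An effect shared by the arrays of a slide could not by itself part all line arrays from all EV arrays. At most 5 probes were on 8 arrays and none of the 4 of any slide, which is another pattern and does not decide this. In the other direction, 85 probes were detected on all 4 arrays of slide 2 and on no other array. That set takes in line arrays, so it does not bear on the source of the 71, for which the same layout holds. The size of the excess stays open. The lowest ratio within a slide, 1.74, came from unequal numbers of arrays. On slide 1, with 2 arrays each and the same number detected, the ratio was 1.39 (705 against 507). Other pairings of those arrays gave 1.53 (145 against 95) and 1.13 (103 against 91), the larger count over the smaller. These rested on far fewer probes. Expression gained in the lines is a hypothesis from the same data, and how far it exceeds expression lost is left open.

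NIATv7_g00327.t1.cds1 was lower on line 136 replicate 2, at 1.80 on the log2 scale relative to the 75th percentile, than on the other arrays of its group. Those lay at 3.01 to 3.19, while the same probe ran from 0.97 to 3.55 in line 107. It was the only such array among 39 groups of 4 examined. Chance gives about 1 in 20 such groups, so a single one is no more than chance gives.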

How the results depend on the processing

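Scaling to spiked-in probes, leaving out slides or array pairs, and the detection alternatives were chosen after seeing the data. Calls for line 107, line 136, both lines and their mean stayed within 1.5 times of the main count under normexp, quantile normalization, median scaling, the authors' table, both filters, slide block and the other variance model, and without any single array. They moved to 2716, 502, 460 and 1792 with position as a block. There the median fold change was 0.868 of the main one and its SE 2.38 times as large. That ratio decides nothing on position because the same arrays chose the probes. The calls moved to 4757, 4546, 3725 and 4642 when at least 2-fold was required, which is a stricter threshold. At an adjusted p under 0.01 the first 3 were 10034, 9590 and 7280. With spiked-in scaling they were 8786, 8103, 6437 and 10332, and the cause was not tested. With fewer arrays, line 107 had 8030 without slide 2, line 136 had 8512 without slide 3, and both together had 6817 and 7636. Line 136 against line 107 gave 200 under median scaling, 143 with no filter, 170 with slide block (fold ratio 0.997, SE ratio 1.04), 3 with position block, 122 with replicate block, 103 with only the groups compared, 113 at 2-fold, 42 at 0.01, 70 with spiked-in scaling, 38 without slide 2, 3 without slide 3 and 116 without EV replicate 4 and line 107 replicate 2. Single arrays left out gave 69 to 282. Apart from stricter thresholds and fewer arrays, the cause was not tested.

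The correlation of fold changes fell to 0.916 with no filter, 0.891 with position block and 0.909 without slide 2, and the cause was not tested. With equal numbers detected, probes on EV arrays alone rose to 121 and those on line arrays alone fell to 386. Same-numbered replicates correlated at -0.285 to 0.126 in their deviations from group means, which gave no sign of pairing. They always lay on different slides, and slide also shaped these deviations. Between arrays of different groups the mean r was 0.120 on the same slide and -0.0547 on other slides. These values therefore cannot exclude that the numbers pair the samples. With the replicate block line 107 had 14214 calls, line 136 13905, both 10958 and the mean 16387. The 4 named probes kept their direction under all alternatives run. The probes that rose have no value with the filter for all 12 arrays. MAX2 and the gene lists gave no value under any alternative. Fits of only the groups compared do not apply to the mean, and thresholds do not apply to the correlation. Signal near background limits the dimmest probes.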

Other observations

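Rises and falls were spread unevenly over brightness. Among kept probes called in both lines, 67.7% rose in the dimmest of 5 equal groups and 36.8% in the brightest. Detection on 4 of 12 arrays lets dim probes that rose in the 8 line arrays pass more easily, and among probes well above background on all 12 arrays these shares were 49.5% and 36.8%. Of the 100 brightest probes, 8 rose, 31 fell and 61 were not called in both lines. As with all directions here, these shares are relative to the 75th percentile of each array.

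Probes of the same gene ID moved together. Of 1803 gene IDs with at least 2 called probes, 29 had calls in both directions, against a mean of 720 of 1305 such IDs when calls were shuffled over 100 draws. In only 2 of these did probes change at least 2-fold each way. Among probes called in both lines, 100 with XLOC identifiers rose and 167 fell, and 5319 with NIATv7 identifiers rose and 5493 fell. With PRID identifiers 431 rose and 513 fell, and with NIATv1 identifiers 66 rose and 73 fell. No test is given for these counts, because probes of a gene ID are not independent and brightness was not matched. What these classes stand for is not given in the sources used here.

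The mean fold changes of NIATv7 gene IDs with adjacent numbers correlated weakly across 10901 pairs, at a Spearman rho of 0.0539, above the highest of 100 shuffles at 0.0251. At a number distance of 2 it was 0.0363 (highest shuffle 0.0254), and at 10 it was -0.00620. At adjacent numbers the correlation was not particular to the comparison with EV. For line 136 minus line 107, a difference not told apart from slide and position, rho there was 0.0695 (highest shuffle 0.0210). At a number distance of 2 that difference gave 0.0213, below its highest shuffle of 0.0258. Whether ID numbers follow chromosome order was not tested.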
